A study of Aedes aegypti with 51 samples.

How the data were processed

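The series holds 51 two-colour custom arrays of hemolymph RNA from adult female Aedes aegypti of the Liverpool strain. Each array set RNA of mosquitoes inoculated with E. coli MG1655 or M. luteus against RNA of naive mosquitoes from the same cohort, at 1, 8 or 24 h. The cDNA was post-labelled with Cy3 and Cy5. Arrays were grouped by bacterium and hour as the titles give them. On 14 of the 51 arrays the source name gave another hour than the title. All 14 were among the 17 M. luteus arrays titled 8 or 24 h, and their source names gave 1 h, while the treatment protocol gave the hour of the title on every array.

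The deposited values are log ratios of both channels of an array, already normalized by the authors, and they were read as log2 ratios. The authors did not state the log base or which channel is the numerator. The deposited values ran from -18.6 to 12.7, too wide for log10 ratios, but a natural log was not excluded, so every fold change rests on the log2 reading. Positive values were read as likely higher in treated than in naive RNA, because arrays not titled as swaps list the treated RNA as channel 1, in Cy5. The 8 arrays titled as dye swaps list naive RNA as channel 1, yet their labels also put treated RNA in Cy5, so the labels and titles disagree about the dyes. The values came in 2 tables, of 39 arrays with 8704 rows and of 12 arrays with 8192 rows, on different platforms. Within a table, the median absolute log ratio was the same on all arrays of a group, so the authors had scaled arrays to each other within each group. Spot filtering, background correction and within-array normalization were not described. Missing values made up 25.5% of the table of 39 arrays and 16.4% of the table of 12.

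Rows offset by 4352 in the 39-array table and by 4096 in the 12-array table correlated at 0.823 and 0.949, against 0.011 and 0.041 or less at neighbouring offsets, so they were taken as replicate spots. Rows of one of the 187 clones that carry a gene symbol were averaged over 4 spots, and other rows over 2 spots, which gave 4165 features in the 39-array table. Only 748 of its 8704 rows carry a gene symbol, and the files give no gene descriptions. For that reason the 25 gene lists fixed by name patterns matched 0 symbols, and no gene group could be tested. Genes are named by their symbol alone. Where a gene has several clones, these are numbered in the order of their identifiers. Gene type and length were taken from the RefSeq table of the AaegL5.0 assembly. The array files name no genome build and no clone sequences were available, so no coordinates are given.

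Technical arrays of one cohort were averaged, so that the cohort was the unit. The comparisons used the 37 arrays of the 39-array table not titled as swaps, from 19 cohorts. Features needed a value in at least 2 cohorts of every group, which left 2871, of which 176 carried a symbol and 173 a single gene. One limma model (limma 3.58.1, R 4.3.3) with a mean for each of the 6 groups was fitted with lmFit and eBayes. Each group mean was tested against 0, the bacteria were compared at each hour, and differences among the hours after each bacterium were tested with limma's moderated F test. All p-values were two-sided and Benjamini-Hochberg adjusted within a comparison, with a threshold of 0.05. For each comparison with naive mosquitoes, the genes named were the 6 clones of a single gene with the highest and the 6 with the lowest mean among those past the threshold and of one sign in every cohort. This gave 59 values for 30 genes. For the hours and the bacteria, clones with a single gene were listed by their test, and genes named outside the rule are said to be so.

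These choices, and the alternatives listed next, were made before the data were examined, except for the averaging of spots, which was set from the row layout before any model was fitted. The alternatives were median centring, scaling of median absolute values between arrays (the log-ratio form of limma's scale method), features with a value on every array, swap arrays kept with their sign as deposited or turned, every array with the cohort as a random block, the replicate number as a random block (limma's duplicateCorrelation, statmod 1.5.0), eBayes with trend and robust, both tables together, and each cohort of a comparison left out. The platforms share identifiers for named clones alone, so both tables together could be fitted for these alone.

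Further alternatives were chosen after the data had been seen. The first was a model that kept the 2 swap arrays of the 39-array table and held a term for dye orientation, with the cohort as a random block, called the dye-term fit. The others were the same model with no block, every row as a feature, the 12-array table alone, a block for the replicate number within an hour, fixed pairs at 24 h, and the data without 2 doubted arrays of the E. coli 1 h group or without cohort 4 at 24 h. The dye-term fit is reported beside each count because swap and other arrays differed strongly.

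The cohort model, the dye-term fit and the fixed pairs were tested on simulated data of the same layout, with 200 changed features per comparison. For the dye-term fit, the simulated noise of swap and other arrays of one cohort was independent. In the data that fit had a block correlation of 0.84, so its recoveries below may not hold for the data. For the cohort model, the simulated cohorts were independent of each other. In the data, cohorts of one replicate number correlated at 0.23 to 0.55 at 24 h after each group's mean was taken off. The recoveries of the cohort model between the bacteria may therefore not hold either. At a log2 size of 2, the cohort model recovered between 68.7% and 91.9% of changed features against naive, and 41.3%, 48.5% and 63.0% between the bacteria at 1, 8 and 24 h. At a log2 size of 1 it recovered between 16.2% and 43.3% against naive, and 4.8%, 12.3% and 18.5% between the bacteria. Against naive, the dye-term fit recovered between 47.8% and 80.6% at a size of 2 and between 3.6% and 33.8% at a size of 1, lowest at 1 h after M. luteus for both. At 8 h it recovered 33.8% after E. coli and 33.3% after M. luteus at a size of 1, and 72.6% and 74.1% at a size of 2. The cohort model recovered 30.8% and 31.7%, and 74.6% and 82.7%, at that hour. Between the bacteria the dye-term fit recovered 50.0%, 67.1% and 70.6% at a size of 2. The fixed pairs at 24 h recovered 54.2% at a size of 2 and 19.4% at a size of 1. Arrays hold no counts, so their number limits the precision. Figures were drawn with matplotlib 3.10.9.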

Results

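Relative RNA levels were measured in hemolymph perfused from adult female Aedes aegypti after inoculation with about 500000 bacteria. Hemolymph is the insect's circulating fluid and carries its blood cells. The 51 arrays comprised 10 at 1 h, 8 at 8 h and 8 at 24 h after Escherichia coli, from 5, 4 and 4 cohorts of mosquitoes. After Micrococcus luteus there were 8 arrays at 1 h, 8 at 8 h and 9 at 24 h, from 4 cohorts at each hour. Every array compared treated with naive mosquitoes of one cohort. No mosquitoes were inoculated without bacteria, so effects of the injury and of the bacteria were not separated. An array held 5076 to 7465 values in the 39-array table and 5348 to 7345 in the 12-array table. The number of arrays limited the precision. Values are normalized log2 ratios, read as treated over naive, with SD across cohorts, and the comparisons rest on 19 cohorts of the 39-array table.

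LOC5579099, LOC5578864 and LOC5580040 kept their sign on the swap arrays of the 39-array table, while many other features turned theirs. On the swap array after E. coli at 8 h, LOC5579099 clone 4 was at 8.33, LOC5578864 at -2.58 and LOC5580040 at -1.46. By contrast, LOC5574055 was at -1.90 there, against a mean of 2.68 on the arrays not swapped. LOC5576963 after both bacteria and LOC5566732 after M. luteus, also named as higher at 8 h, turned too. The other clones named as lower at 8 h lay between -1.62 and -0.00 on the swap array of their group. Of the features called at 8 h, 44.0% after E. coli (395 of 897 with a value) and 50.2% after M. luteus (436 of 869) had the opposite sign on the swap array. Technical replicates correlated over features with a median r of 0.76 and the 2 swap arrays at 0.82, but swap arrays correlated with other arrays at a median of 0.06. Features are not independent replicates, so these r describe the arrays. Of the 59 values of named genes against naive, 40 were also called with the same sign in the dye-term fit, and the others are pointed out below. This fit estimated the dye component from 2 swap arrays at 8 h and carried it to the other hours.

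**Figure D1:**
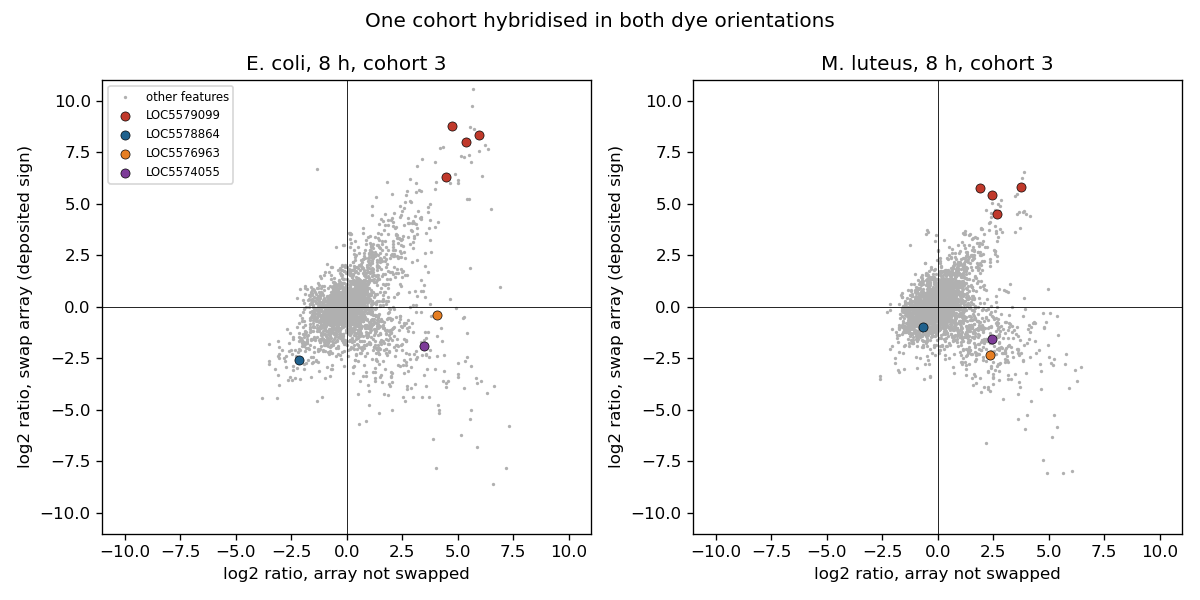
Log2 ratio of each feature on the array not swapped of cohort 3 at 8 h (horizontal) against its log2 ratio on the swap array of the same cohort (vertical), after E. coli and after M. luteus. Coloured points are clones of 4 named genes. Features high on the array not swapped spread into an upper and a lower arm, and the correlation over features was 0.26 after E. coli and -0.07 after M. luteus.

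At 1 h after E. coli, LOC5579099 clone 3 was 5.03-fold higher than in naive mosquitoes, at a log2 ratio of 2.33 ± 1.49 (SD, n = 3, adjusted p = 0.024). The other 3 clones of this gene had means of 1.49, 1.60 and 2.09 and did not pass the threshold (adjusted p = 0.22, 0.61 and 0.059). LOC5565037 was 2.82-fold lower, at -1.50 ± 0.97 (SD, n = 3, adjusted p = 0.042). In the 2 other cohorts, of the 12-array table, these means were 3.43 and -1.02. These were the only 2 of 173 single-gene clones called, and both were also called in the dye-term fit, though LOC5565037 was not without its cohort block (adjusted p = 0.13). Keeping the swap arrays, which are at 8 h, as deposited ended both calls (adjusted p = 0.055 and 0.064), and so did turning them (adjusted p = 0.2 and 0.072). Both means stayed at 2.33 and -1.50, so only the spread shared by the groups and the adjustment moved. With trend and robust LOC5565037 had an adjusted p of 0.051. Both calls rested on cohort 3: without it LOC5579099 clone 3 was at 1.49 (adjusted p = 0.36) and LOC5565037 at -1.02 (adjusted p = 0.45). LOC5565037 also lost its call without cohort 5, at -1.48 (adjusted p = 0.14). Among all 2871 features, 124 were called, 120 higher and 4 lower, so that 96.8% were higher. With scaling between arrays, 373 were called and 82.3% were higher. Without cohort 3 the count was 9, and without cohort 4 it was 73. Leaving out 2 doubted arrays, the second of cohort 4 and the first of cohort 5, gave 265. With the dye term 254 were called, 140 higher and 114 lower. Of these, 75 were among the 124 with the same sign, and 28 of the 124 had the opposite sign there.

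At 8 h after E. coli, all 4 clones of LOC5579099 were higher, with means between 4.00 and 5.38. Clone 4 was 41.5-fold higher, at 5.38 ± 0.52 (SD, n = 3, adjusted p = 5.9e-06), and stood at 5.94 in the 1 cohort of the 12-array table. The gene is protein-coding, with a length of 641 bp in AaegL5.0. Its nearest protein-coding neighbour, LOC5579095, has the same length, and whether the clones also bind that gene's RNA was not tested. LOC5578864 was 3.7-fold lower, at -1.89 ± 0.51 (SD, n = 3, adjusted p = 0.00017), and stood at -1.75 in the 12-array table. LOC5564545 at -1.54 ± 0.35 and LOC5580040 at -1.49 ± 0.40 were also lower (adjusted p = 0.00057 and 0.00082), and both were called in the dye-term fit. They were nearer 0 in the 12-array table, at -0.50 and -0.62. LOC5564226 clone 2 at -1.63, LOC5565962 clone 4 at -1.48 and LOC5564041 at -1.47 were called here but not in the dye-term fit (adjusted p = 0.059, 0.22 and 0.26). In the 12-array table these were at -0.78, -0.82 and -0.29. The other clones of LOC5564226 and LOC5565962 were not called, with means of 0.29 for the first gene and -0.24, -0.26 and -0.43 for the second. LOC5576963 fell from 3.41 to 1.17 with the dye term (adjusted p = 0.02), and LOC5574055 from 2.68 to 0.26 (adjusted p = 0.84). These stood at 2.08 and 0.55 in the 12-array table.

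Of the 173 single-gene clones, 44 were called at 8 h after E. coli, 21 higher and 23 lower. The dye-term fit kept 20 of these with the same sign, 11 higher and 9 lower. Among all features 922 were called, 664 higher and 258 lower. With the dye term 487 were called, 329 higher and 158 lower. Of these, 383 were among the 922 with the same sign, and 123 of the 922 had the opposite sign there. Without cohort 2, 3 or 4 in turn, LOC5579099 clone 2 was at 4.17, 3.63 and 4.20 (adjusted p = 0.068, 0.11 and 0.062), LOC5564226 clone 2 at -1.78, -1.41 and -1.71 (adjusted p = 0.054, 0.12 and 0.061) and LOC5565962 clone 4 at -1.49, -1.64 and -1.31 (adjusted p = 0.12, 0.082 and 0.16). LOC5564041 lost its call without cohort 3, at -1.42 (adjusted p = 0.098), and without cohort 4, at -1.06 (adjusted p = 0.2). With the sign of the swap array turned, the 4 clones of LOC5579099 lay between 1.75 and 2.99 (adjusted p between 0.051 and 0.47), LOC5578864 at -1.10 (adjusted p = 0.089) and LOC5580040 at -1.01 (adjusted p = 0.068). LOC5564226 clone 2, LOC5565962 clone 4 and LOC5564041 were not called with it turned (adjusted p = 0.21, 0.14 and 0.13), nor the last 2 with it as deposited (adjusted p = 0.076 and 0.066).

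At 24 h after E. coli, LOC5579099 clone 4 was 86.3-fold higher, at 6.43 ± 1.56 (SD, n = 4, adjusted p = 4.3e-07), and clones 1 and 3 were at 5.63 and 5.06. Clone 2 was not called, at 2.19 (adjusted p = 0.159): it was at -0.94 in cohort 4, where the other 3 clones were between 5.39 and 7.95. LOC5578841, annotated as a pseudogene of 622 bp, was 12.2-fold higher, at 3.60 ± 1.77 (SD, n = 4, adjusted p = 0.00093). LOC5565507 was 8-fold higher, at 3.00 ± 0.60 (SD, n = 4, adjusted p = 1.4e-07), with cohorts between 2.47 and 3.68. LOC5564226 clone 2 was 6.6-fold lower, at -2.72 ± 0.80 (SD, n = 4, adjusted p = 0.00019), while clone 1 of that gene was at 0.27 and not called. LOC5574872 was at -1.84 ± 0.29 (SD, n = 3, adjusted p = 0.00013). Clone 2 of the long non-coding RNA LOC5571086 was at -1.73 ± 0.61 (SD, n = 4, adjusted p = 0.00099), and its clones 1 and 3 were at 0.11 and -0.44, not called. LOC5572474 clone 1 was at -1.41 ± 0.28 (SD, n = 4, adjusted p = 0.0029), with adjusted p = 0.044 in the dye-term fit and 0.086 in that fit without the cohort block.

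Of the other genes named at 24 h after E. coli, LOC5569903 at -1.60 and LOC5564041 at -1.57 were not called in the dye-term fit (adjusted p = 0.096 and 0.12). LOC5569903 lost its call without cohort 2, at -1.03 (adjusted p = 0.13), and without cohort 3, at -1.53 (adjusted p = 0.063). LOC5576963 was at 1.41 ± 0.42 (SD, n = 4, adjusted p = 0.0012), but the dye-term fit put it at -0.86 (adjusted p = 0.049). Of the 173 single-gene clones 45 were called, 11 higher and 34 lower, and 19 of these were kept with the dye term, 6 higher and 13 lower. Among all features 1175 were called, 646 higher and 529 lower. The dye-term fit called 697, with the balance turned to 296 higher and 401 lower, and to 246 and 291 without its cohort block. Of the 697, 499 were among the 1175 with the same sign, and 224 of the 1175 had the opposite sign there.

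At 1 h after M. luteus, with 2 cohorts in the 39-array table, LOC5569847 was 4.81-fold lower, at -2.27 ± 1.50 (SD, n = 2, adjusted p = 0.004). LOC5572383 was 3.33-fold lower, at -1.74 ± 0.16 (SD, n = 2, adjusted p = 0.004), with cohorts at -1.63 and -1.85. LOC5566725, LOC5565037, LOC5572082 and LOC5576650 were lower, with means of -2.12, -2.01, -1.87 and -1.53 (adjusted p = 0.041, 0.017, 0.021 and 0.017). LOC5564545 was 3.56-fold higher, at 1.83 ± 1.03 (SD, n = 2, adjusted p = 0.006), and LOC5575441 and LOC5564713 were at 1.54 and 1.40 (adjusted p = 0.017 and 0.039). In the 2 other cohorts, of the 12-array table, LOC5564545, LOC5575441 and LOC5564713 were at -0.85, -0.11 and -0.10, and LOC5566725 at 0.16. The other 5 genes lay between -0.80 and -0.07 there, with LOC5572383 at -0.07. None of the genes named here was called in that table. No clone of LOC5579099 was called, with means between -1.40 and 2.02, while in the 12-array table they lay between 0.78 and 1.10 in cohort 1 and between 2.18 and 2.68 in cohort 2. Only LOC5564713 was not called in the dye-term fit (adjusted p = 0.18).

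Leaving out cohort 3 after M. luteus at 1 h ended the calls of LOC5564545 at 1.10, LOC5575441 at 1.01, LOC5564713 at 0.34, LOC5569847 at -1.21 and LOC5576650 at -0.77 (adjusted p = 0.11, 0.2, 0.65, 0.075 and 0.27). Leaving out cohort 4 ended those of LOC5566725 at -1.35, LOC5565037 at -1.07 and LOC5572082 at -1.36 (adjusted p = 0.35, 0.28 and 0.2), and put LOC5564713 at 2.47. Scaling between arrays ended the calls of LOC5564713, LOC5566725, LOC5565037, LOC5572082 and LOC5576650 (adjusted p = 0.092, 0.11, 0.067, 0.065 and 0.058). The dye-term fit without the cohort block ended those of LOC5564713, LOC5566725 and LOC5576650 (adjusted p = 0.24, 0.088 and 0.053). Keeping the 8 h swap arrays as deposited or turned left LOC5564713 at 1.40, with an adjusted p of 0.056 or 0.053. With both tables LOC5575441 was at 1.04 (adjusted p = 0.06). Of the 173 single-gene clones 16 were called, 3 higher and 13 lower, and 10 were kept with the dye term, 2 higher and 8 lower. Among all features 337 were called, 156 higher and 181 lower, so that 46.3% were higher. Over features, arrays of cohort 3 correlated with those of cohort 4 at only 0.08 to 0.22. Technical arrays of one cohort correlated at 0.82 and 0.86, so the 2 cohorts shared little of their profile. With scaling between arrays 109 were called and 35.8% were higher. In the 12-array table the balance differed, with 244 called, 188 higher and 56 lower. With the dye term 388 were called, 156 higher and 232 lower. Of these, 187 were among the 337 with the same sign, and 31 of the 337 had the opposite sign there.

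At 8 h after M. luteus, LOC5579099 clone 4 was 11.1-fold higher, at 3.47 ± 0.54 (SD, n = 3, adjusted p = 0.00032). Clones 1 and 3 were at 2.42 and 2.28, and clone 2 was at 1.96 and not called (adjusted p = 0.25). On the swap array clones 4, 1 and 3 were at 5.83, 5.45 and 4.51, and in the 12-array table at 4.49, 4.53 and 3.97. LOC5578864 was 2.57-fold lower, at -1.36 ± 0.66 (SD, n = 3, adjusted p = 0.003), with -1.45 in the 12-array table. LOC5580040 at -1.15 ± 0.45 and LOC5574304 at -1.14 ± 0.45 were also lower (adjusted p = 0.0067 and 0.0092) and were called in the dye-term fit. Without its cohort block LOC5574304 was not (adjusted p = 0.057). In the 12-array table, with 1 cohort, they were at -0.41 and -0.69. LOC5569566 at -1.12, LOC5565544 clone 2 at -1.03 and LOC5569847 at -1.01 were not called in the dye-term fit (adjusted p = 0.083, 0.062 and 0.24), and stood at -0.35, -0.40 and -0.66 in the 12-array table. The dye term took LOC5576963 from 2.58 to 0.27, LOC5574055 from 2.37 to 0.16 and LOC5566732 from 2.12 to -0.27, none of them called there. In the 12-array table, where every 8 h array was titled as a swap, these genes were at 1.94, 0.68 and -0.48.

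Without cohort 4 after M. luteus at 8 h, LOC5578864 was at -1.05, LOC5580040 at -0.94 and LOC5574304 at -0.96 (adjusted p = 0.056, 0.076 and 0.087). Without cohort 2, LOC5574304 was at -1.07 and LOC5565544 clone 2 at -0.94 (adjusted p = 0.065 and 0.056). LOC5569847 lost its call without cohort 2, 3 or 4 (adjusted p = 0.12, 0.071 and 0.096), and LOC5566732 without cohort 3, at 1.00 (adjusted p = 0.12). With the sign of the swap array turned, LOC5579099 clones 4, 1 and 3 were at 1.87, 1.11 and 1.08 (adjusted p = 0.26, 0.52 and 0.47), LOC5578864 at -1.09 (adjusted p = 0.094), LOC5580040 at -0.77 (adjusted p = 0.17) and LOC5574304 at -0.95 (adjusted p = 0.074). LOC5565544 clone 2 and LOC5569847 were not called with it turned (adjusted p = 0.083 and 0.1), nor LOC5569847 with it as deposited (adjusted p = 0.081). Of the 173 single-gene clones 39 were called, 12 higher and 27 lower, and 8 were kept with the dye term, 3 higher and 5 lower. Among all features 889 were called, 638 higher and 251 lower. The count was 582 without cohort 2 and 586 without cohort 4. The dye-term fit called 353, 219 higher and 134 lower. Of these, 272 were among the 889 with the same sign, and 112 of the 889 had the opposite sign there.

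At 24 h after M. luteus, LOC5579099 clone 4 was 47.4-fold higher, at 5.57 ± 0.87 (SD, n = 4, adjusted p = 2.1e-06), and clones 1 and 3 were at 5.12 and 4.76. Clone 2 was at 2.18 (adjusted p = 0.187), with -2.07 in cohort 4. LOC5578841 was 8.43-fold higher, at 3.08 ± 0.40 (SD, n = 4, adjusted p = 0.0039), and LOC5565507 7.85-fold higher, at 2.97 ± 0.46 (SD, n = 4, adjusted p = 1.1e-07). LOC5564226 clone 2 was 4.34-fold lower, at -2.12 ± 1.40 (SD, n = 4, adjusted p = 0.0021), while its clone 1 was at 0.35 and not called. LOC5566725 was at -1.59 ± 1.47 (SD, n = 4, adjusted p = 0.014), but at -0.88 without cohort 3 (adjusted p = 0.13) and with adjusted p = 0.11 in the dye-term fit without the cohort block. LOC5573361 clone 1 at -2.46, LOC5564041 at -1.36, LOC5572735 at -1.31 and LOC5572478 at -1.31 were not called in the dye-term fit (adjusted p = 0.057, 0.26, 0.07 and 0.19). The dye-term fit put LOC5574055 at -1.09 in place of 1.23, and did not call it (adjusted p = 0.067).

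Leaving out cohort 3 after M. luteus at 24 h put LOC5573361 clone 1 at -1.57 and LOC5572478 at -0.74, without a call (adjusted p = 0.26 and 0.27). Without cohort 4, LOC5573361 clone 1 was at -2.24 (adjusted p = 0.15), LOC5564041 at -1.33 (adjusted p = 0.063) and LOC5572735 at -0.79 (adjusted p = 0.035). LOC5564041 and LOC5572478 also lost their calls without cohort 1 (adjusted p = 0.065 and 0.076) or cohort 2 (adjusted p = 0.063 and 0.053). With every array and the cohort as a random block, LOC5573361 clone 1 and LOC5574055 were not called (adjusted p = 0.14 and 0.054). With the 8 h swap arrays as deposited LOC5572478 stayed at -1.31 but was not called (adjusted p = 0.052). Of the 173 single-gene clones 32 were called, 9 higher and 23 lower, and 12 were kept with the dye term, 5 higher and 7 lower. Among all features 875 were called, 531 higher and 344 lower. With the dye term 572 were called, 270 higher and 302 lower, but without its cohort block it called 427, 238 higher and 189 lower. Of the 572, 370 were among the 875 with the same sign, and 221 of the 875 had the opposite sign there.

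The series title names phagocytosis and melanization, and the comparison of the bacteria asks whether the responses to E. coli and M. luteus differed. At 24 h, LOC5565507 differed by 0.03 (E. coli minus M. luteus, 95% interval -0.61 to 0.66) and LOC5579099 clone 4 by 0.86 (-0.69 to 2.42). At 8 h, LOC5579099 clones 1, 3 and 4 were higher after E. coli by 2.27 (0.41 to 4.14), 2.18 (0.54 to 3.82) and 1.91 (0.11 to 3.70), but the adjusted p was 1 for each. The 12-array table has 1 cohort per bacterium at 8 h. There these clones were at 5.62, 5.27 and 5.94 after E. coli, and at 4.53, 3.97 and 4.49 after M. luteus. LOC5578864 differed by -0.53 at 8 h (-1.46 to 0.40). At 1 h, LOC5564545 was at -0.54 after E. coli and 1.83 after M. luteus, a difference of -2.37 (-3.34 to -1.40, adjusted p = 0.11). In the 12-array table the direction was opposite, with cohorts at -0.56 and -0.49 after E. coli and -0.55 and -1.15 after M. luteus. With a block for the replicate number within an hour its adjusted p was 0.029, but cohorts of one number correlated at 0.05 and -0.46 at 1 h, so the numbers did not pair them. With 2 M. luteus cohorts, such r come in opposite pairs and are not separate checks. E. coli cohort 5 and M. luteus cohort 4 correlated at 0.55, and a pairing under other numbers was not tested. At 24 h, LOC5573361 clone 1 was at 0.73 after E. coli and -2.46 after M. luteus, a difference of 3.19 (0.72 to 5.67, adjusted p = 1). Between cohorts of one number, 1, 3 and 4, clone 1 differed by 4.15, 3.52 and 1.91. With 1 cohort left out the difference lay between 1.60 and 4.31 (adjusted p = 1 in each case), and clone 2 of that gene differed by -0.24 (-1.49 to 1.02). The genes in this paragraph were chosen after their values were seen. In limma, 0 of 2871 features were called at 1, 8 and 24 h, with 261, 49 and 35 at an unadjusted p under 0.05, where chance gives 143.6. The counts at 8 and 24 h lie below chance, so the test may be too strict there. At 24 h, cohorts of one number correlated at 0.23 to 0.55 after each group's mean was taken off. A test that ignores such pairs is too strict. With fixed pairs at 24 h the unadjusted count was 155, near the 143.6 of chance, so the pairing may account for the low count there. The cause at 8 h was not tested. The dye-term fit also called 0 at each hour, with 236, 43 and 32 unadjusted. At 1 h the count rose to 2 without E. coli cohort 5, to 39 without M. luteus cohort 3 and to 84 without M. luteus cohort 4.

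LOC5565507 differed among the hours after both bacteria. After E. coli its means were 0.13, 0.77 and 3.00 at 1, 8 and 24 h (adjusted p = 0.00052), and after M. luteus 0.92, 0.40 and 2.97 (adjusted p = 0.00092). LOC5579099 clone 4 was at 2.09, 5.38 and 6.43 after E. coli (adjusted p = 0.026), and clone 3 at 1.02, 2.28 and 4.76 after M. luteus (adjusted p = 0.048). LOC5578864 was at -0.16, -1.89 and -0.13 after E. coli (adjusted p = 0.038). LOC5576963 was at 0.50, 3.41 and 1.41 after E. coli (adjusted p = 0.0099). LOC5564545 was at 1.83, -0.89 and -0.58 after M. luteus (adjusted p = 0.02), with a mean of -0.85 at 1 h in the 12-array table. With LOC5579099 clone 1 after E. coli (adjusted p = 0.028), these were the 5 and 3 single-gene clones called. A dye effect that is alike at each hour drops out of these differences, so the dye-term fit, which also called them, is no check on it.

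In all, 90 features differed among the hours after E. coli and 36 after M. luteus. Of the 90, 63 were higher at both 8 and 24 h than at 1 h, 14 were lower at both, and 13 were mixed. Of the 36, 28 were higher at both, 2 lower at both and 6 mixed. The dye-term fit called 37 of the 90 and 26 of the 36, and none beyond these. The count after E. coli was 9 and 33 without cohorts 4 and 5 at 1 h, 59, 34 and 48 without cohorts 2, 3 and 4 at 8 h, and 36 and 37 without cohorts 3 and 4 at 24 h. Without 2 doubted arrays of the E. coli 1 h group it was 53, and the count after M. luteus was 63. The count after M. luteus was 67 and 382 without cohorts 3 and 4 at 1 h, 13, 9 and 10 without cohorts 2, 3 and 4 at 8 h, and 7 without cohort 4 at 24 h.

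**Figure D2:**
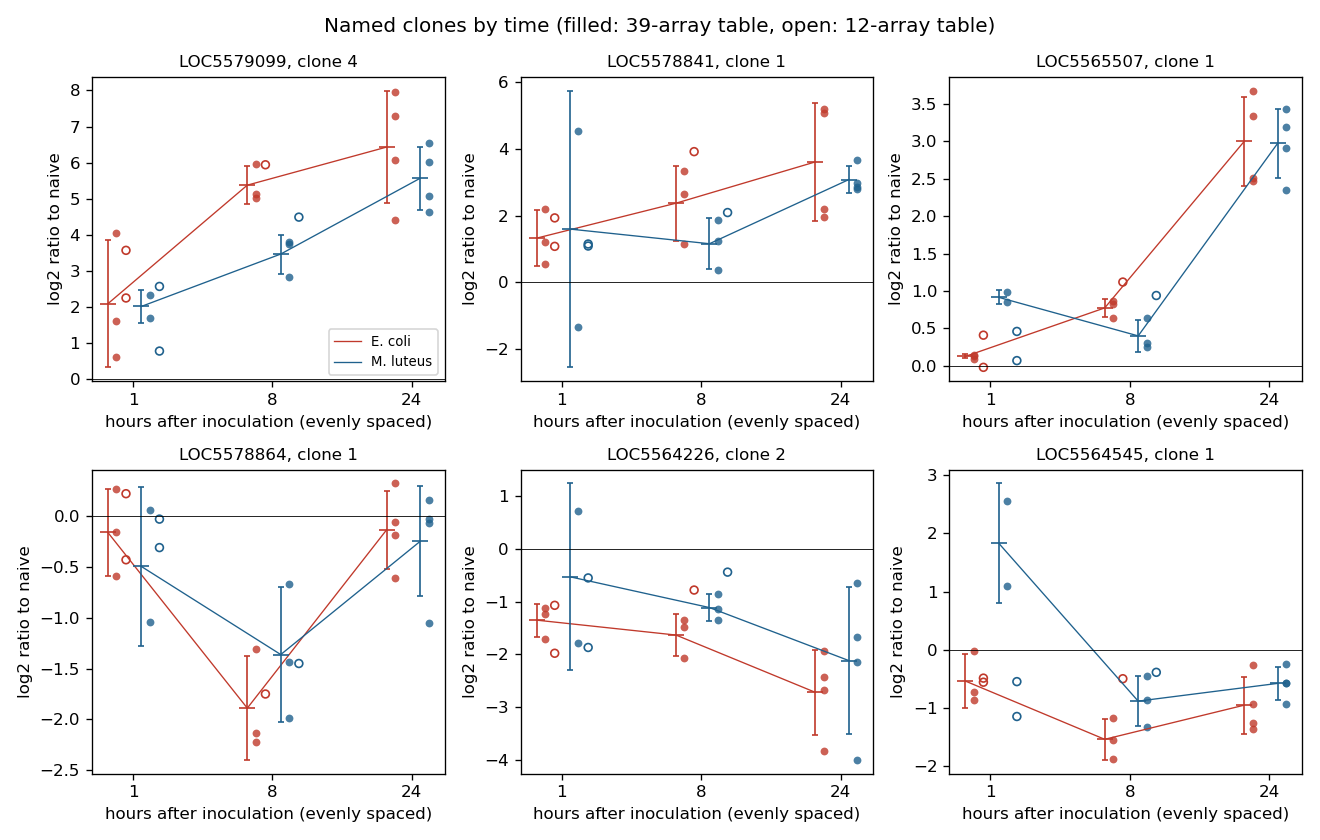
Log2 ratio of treated over naive for LOC5579099 clone 4, LOC5578841, LOC5565507, LOC5578864, LOC5564226 clone 2 and LOC5564545, a panel each, by hour after E. coli or M. luteus, with hours evenly spaced. Points are cohorts, filled for the 39-array table and open for the 12-array table, and bars are the mean ± SD of the 39-array cohorts, with lines joining the means. LOC5565507 lies between 2.35 and 3.68 in every cohort at 24 h, and LOC5579099 clone 4 between 4.41 and 7.95.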

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

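The dye-component test, the 12-array and spot-correlation tests, and the test of mixed sets were chosen after their results had been seen, as were the dye-term fits and the data without cohort 4.

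The features that differed among the hours, 90 after E. coli and 36 after M. luteus, stand out because a test of the difference between time points called them. For E. coli, 2 of 100 splits of the 10 cohorts gave as many features as the real split, itself included, and the highest other split gave 99. That share is under 0.05 by a narrow margin. The authors had scaled arrays within each hour, to a median absolute log ratio of 0.528, 0.658 and 0.770 at 1, 8 and 24 h. The splits mix these scales, so they cannot exclude chance. The splits were run for E. coli alone, so the count after M. luteus was not tested in this way. Among 38 groups tested for an outlying sample, 2 held one, which is near the 1 in 20 that chance gives for independent values. Some groups held technical arrays of one cohort, and others held genes chosen by their values, so that rate is approximate. One outlying sample was the first array of cohort 5 at 1 h after E. coli, whose replicate spots correlated at 0.45. The other was LOC5572474 clone 1 in cohort 3 at 24 h after E. coli, at -1.82.

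Many features called at 8 h turned sign on the swap array of their group. Swap arrays deposited with the wrong sign are argued against in both tables. In the 39-array table, the E. coli minus M. luteus difference on the swap arrays, from which a shared dye effect drops out, correlated at 0.25 with that of cohorts 2 and 4. In the 12-array table, the 8 h minus 1 h difference of the E. coli swap arrays correlated over 173 named clones at 0.62 with that of the 39-array table, and at 0.49 without LOC5579099. The M. luteus 8 h swap arrays, set against the same E. coli 1 h arrays, gave 0.45. Poor hybridisation is argued against by replicate spots that correlated at 0.84 and 0.93 on the swap arrays, within or above the range of 0.82 to 0.92 of the other 8 h arrays. A dye-specific signal may account for the pattern, but its test does not single it out. The component that turned with the dyes correlated at 0.88 between the cohorts of the 2 bacteria. Its SD was 0.96 and 0.95, against 1.25 and 0.88 for the mean of both orientations. Between the bacteria, the arrays not swapped of these cohorts correlated at 0.80 and the swap arrays at 0.82. That component would therefore correlate under any cause shared by the 2 swap arrays. The 8 h arrays of the 12-array table, all titled as swaps, correlated over named clones with the means of arrays not swapped. The r was 0.81 after E. coli and 0.65 after M. luteus, and 0.61 and 0.45 without LOC5579099. The cohorts of the 2 swap arrays share their number and perhaps naive RNA or a day of work, so a batch effect of these arrays remains open.

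At 24 h, arrays of cohort 4 correlated more across the bacteria (up to 0.853) than within them (0.578 and 0.603). Exchanged labels of the second technical arrays may account for this: the E. coli minus M. luteus difference of the second arrays correlated at -0.35 with that of cohorts 1 to 3, against 0.31 for the first arrays. Arrays made in sets that mix the bacteria may also account for it. Of the 2 other cohorts with enough arrays, 0 had a correlation across the bacteria above those within by more than their range (0.864 against 0.715 to 0.855 in cohort 1, and 0.792 against 0.844 to 0.897 in cohort 2), and sets in cohort 4 alone are not excluded by this. The first and second differences would be nearly opposite under either explanation, which cannot be told apart here. No biological explanation was tested, since the arrays within a cohort are technical replicates.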

How the results depend on the processing

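The dye-term fits, every row as a feature, the 12-array table alone, the block within an hour, the fixed pairs, and the data without doubted arrays or without cohort 4 at 24 h were chosen after the data had been seen. The cause of the shifts below was not tested, except that every row as a feature tests more items and leaving out cohorts leaves fewer samples. At 1 h in the 39-array table, the deposited median absolute log ratio was 0.528 after E. coli and 0.766 after M. luteus. The 1 h comparison of the bacteria thus set ratios of unlike scale against each other. Scaling between arrays evens these scales, and it also called 0 features in that comparison.

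Counts within 1.5 times their first value are not repeated. At 1 h after E. coli, the count of 124 became 373 with scaling between arrays, 50 with swap arrays as deposited, 26 with them turned, 254 with the dye term, 230 with the dye term and no cohort block, 189 with every row, 324 in the 12-array table, 265 without 2 doubted arrays, and 9 to 102 with a cohort left out. At 8 h after E. coli, the 922 became 482 with swap arrays turned, 487 and 602 with the dye term with and without the block, and 1658 with every row. At 24 h after E. coli, the 1175 became 697, 537 and 1930 under the last 3 of these. At 1 h after M. luteus, the 337 became 109 with scaling and 538 with every row. At 8 h after M. luteus, the 889 became 569 and 477 with swap arrays as deposited and turned, 353 and 496 with the dye term with and without the block, 1572 with every row, and 582 to 603 with a cohort left out. At 24 h after M. luteus, the 875 became 572, 427 and 1457 with the dye term with and without the block and with every row. Between the bacteria at 1 h, the 0 became 4 with a value on every array, 6 with the cohort as a random block, 4 with the block within an hour, and 0 to 84 with a cohort left out. A lone remaining cohort of M. luteus at 1 h is assumed to vary like the other groups. Between the bacteria at 8 and 24 h, every alternative run gave 0.

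Among the hours after E. coli, the 90 became 28 and 6 with swap arrays as deposited and turned, 31 with trend and robust, 37 and 177 with the dye term with and without the block, 151 with every row, 53 without doubted arrays, 23 without cohort 4 at 24 h, and 9 to 130 with a cohort left out. After M. luteus, the 36 became 118 with a value on every array, 13 and 3 with swap arrays as deposited and turned, 121 with the cohort as a random block, 23 with trend and robust, 72 with the dye term and no block, 59 with every row, 63 without doubted arrays, 10 without cohort 4 at 24 h, and 7 to 382 with a cohort left out.

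Over the 59 values of named genes, the alternatives gave 949 values, of which 805 kept sign and call, 134 kept the sign without the call and 10 turned sign. Most of these are refits of the arrays from which the genes were chosen, so the share that held is partly built in. In the 12-array table, which holds other cohorts, 5 of 35 values turned sign. At 1 h, where that table has 2 cohorts per bacterium, both E. coli calls held there, but no M. luteus call did. LOC5576963 at 24 h after E. coli was at -0.86 and -0.77 with the dye term with and without the block, and LOC5574055 at 24 h after M. luteus at -1.09 and -0.90. LOC5566732 at 8 h after M. luteus was at -0.27 with the dye term and -0.48 in the 12-array table. At 1 h after M. luteus, LOC5564545, LOC5575441, LOC5564713 and LOC5566725 were at -0.85, -0.11, -0.10 and 0.16 in the 12-array table. The 12-array table has 1 cohort per bacterium at 8 h, assumed to vary like its other groups. Leaving out doubted arrays or cohort 4 was run for named genes in comparisons that use those arrays. Both tables together could be fitted for named clones alone. The gene-list alternatives were not run, since the lists matched 0 genes. The files give no signal over background, so its limits are unknown.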

Other observations

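The 12-array table holds cohorts that the comparisons did not use, and its genes were chosen after their values were seen. At 8 h it has 1 cohort per bacterium, on arrays titled as swaps, so its 8 h values are given without a test. LOC5570068 was at 2.54 after E. coli and 2.17 after M. luteus, against 0.92 and 0.45 in the 39-array table, where it was not called. LOC5580034 was at 2.31 and 1.89, LOC5572082 at 2.10 and 1.66, LOC5567470 at 1.93 and 1.84 and LOC5569016 at 1.76 and 1.57. LOC5574783 was at -2.27 and -2.23, with -1.42 and -0.86 in the 39-array table (adjusted p = 0.0032 and 0.058).

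At 1 h, the 12-array table has 2 cohorts per bacterium, and 10 single-gene clones were called after E. coli and 4 after M. luteus. One of the E. coli cohorts was on swap arrays. All 4 clones of LOC5579099 were higher after E. coli, between 2.91 and 3.43, and above 0 but not called in both M. luteus cohorts, between 0.78 and 2.68. LOC5578841 was at 1.51 after E. coli (adjusted p = 0.023). LOC5578361 was lower at -1.58 and -1.96, LOC5566220 at -1.45 and -2.25, and LOC5569903 at -2.32 and -2.30 after E. coli and M. luteus. LOC5565962 clone 1 was lower after M. luteus, at -2.83 (adjusted p = 0.044), and also low after E. coli, with cohorts at -3.29 and -1.17, as was clone 3 after both bacteria. None of these last 4 genes was called at 1 h in the 39-array table, where LOC5566220 was at 0.12 and 1.12. Over named clones, group means of both tables correlated at 0.51 and 0.81 at 1 and 8 h after E. coli and at 0.07 and 0.65 after M. luteus. Without LOC5579099 these were 0.19, 0.61, -0.04 and 0.45.

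The cohort model called no feature between the bacteria, although at 1 h some alternatives called 4 or 6, and up to 84 with a cohort left out. For 24 h, cohort differences that hide a difference between the bacteria were weighed, in a test chosen after the counts had been seen. Replicate numbers paired the cohorts at 24 h, where cohorts of one number correlated at 0.55, 0.51, 0.23 and 0.44 after each group's mean was taken off. With the number as a fixed term, limma called 0 features at 24 h, with 155 at an unadjusted p under 0.05. On simulated data that fit recovered 19.4% of features changed by a log2 size of 1 and 54.2% at a size of 2, so the explanation stays open. LOC5573361 clone 1 had an adjusted p of 0.83 there. The fit included cohort 4, whose arrays may carry exchanged labels (-0.35) or come from mixed sets. All 35 splits of the 8 cohorts at 24 h and all 10 splits at 8 h gave 0 features, but any split reaches a real count of 0, so the splits say nothing about chance here. The cohort model could also have missed a smaller difference. On simulated data it recovered 18.5% of features changed by a log2 size of 1 at 24 h. The simulated cohorts were independent, unlike those of the data, so this share may not hold.

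For the counts against naive, turning the sign of whole cohorts gave too few splits for a share under 0.05. With 4 ways to turn the signs, 1 gave as many features as the real one at 1 h after E. coli (124, highest other 0), at 8 h after E. coli (922, highest other 2) and at 8 h after M. luteus (889, highest other 1). With 8 ways, 1 did at 24 h after E. coli (1175, highest other 4) and at 24 h after M. luteus (875, highest other 0).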
